A study of Mus musculus with 78 samples.

How the data were processed

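Liver RNA of 78 female mice, extracted with TRIzol and RNeasy per the labels' protocols, had been hybridised to an Affymetrix mouse array, 1 array per mouse. The deposited table held 1 column per sample with log2 expression values for 35556 probe sets. RMA and Partek 6.5 are named in the submitters' processing notes, without their role or order. The deposited log2 values ran from 1.79 to 14.6, with array medians of 5.35 to 5.65. How the arrays had been scaled to one another is not stated. No raw intensities were analysed here, and livers had been frozen or kept in RNAlater per the labels' protocols, which do not say which sample was which. No pair of the 78 columns was identical (0 pairs, highest Pearson r between arrays 0.997). For arrays, the number of animals sets the precision.

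The samples fell into 18 groups by their labels. The age series held 48 arrays, 4 each of Npc1-/- and Npc1+/+ females from heterozygote crosses at each of 6 ages from 1 to 11 weeks. The 12-week set held 30 arrays of BALB/cJ females, 5 per group, with oligos and NAC given from 8 to 12 weeks of age. All samples were used.

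Probe sets were matched to gene symbols through the probe table. Of these, 21789 had 1 symbol, 1621 had several and 12146 were not listed. Each of 19938 genes was represented by its probe set with the highest mean over the 78 arrays, a choice among several for 999 genes. The array annotation names no genome build, so no coordinates are given. A gene entered a test when its value was above the median of all values (5.54) in at least 4 arrays of the fit, which left 12638 genes in the age series, 11900 in the 12-week set and 12748 over all arrays. The values carry no detection calls. Of 1293 pairs of a gene open to naming and a contrast of 2 groups, 171 had a group mean below 5.54, and a change from a level at background is a lower bound.

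Differences were estimated with limma 3.58.1 in R 4.3.3, by lmFit with 1 mean per group and eBayes, separately for the age series and the 12-week set. Tests were two-sided, and Benjamini-Hochberg adjusted p-values under 0.05 over all genes tested in a contrast counted as past the threshold. The contrasts were the genotype difference at each of 6 ages, its mean over the ages with equal weights, its linear slope per week, its variation between ages (moderated F test), and the age effect in Npc1+/+ mice (moderated F test). In the 12-week set they were the Npc1 oligo against the control oligo without and with NAC, NAC against no NAC under each oligo, the interaction of both, fasted against untreated, and control oligo against untreated. The genotype effect at 11 weeks minus the oligo effect was tested in a fit of all 78 arrays, and apart from it the age series and the 12-week set were compared only in the correlation and counts of their effects across genes, described below.

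The 39 gene lists were fixed before the data were examined, as were the contrasts, the tests, the filter and all alternatives except 4, which leave out arrays with signal of another organ. Lists were tested with limma's camera at its preset correlation of 0.01 in 16 contrasts, with Benjamini-Hochberg adjustment over the lists of a contrast, and again with a correlation estimated for each list. The count of list members past the threshold is given over all genes tested and adjusted over the list alone. A list's level in a mouse is the mean log2 value of its members. The effects of genotype and oligo were compared by Pearson and Spearman correlation across genes and by counts of genes past the threshold in both, against the number expected of independent lists.

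Genes are named by a rule set at the same time. It takes Npc1, the 10 highest and 10 lowest genes of the averaged contrast with the same sign at all 6 ages, and the 5 highest and 5 lowest at each age, for the slope, and for 11 against 1 week in Npc1+/+ mice. It further takes the 10 highest and 10 lowest of each other contrast and up to 4 members of each described list, those past the threshold with the largest change. Clone names are left out, and fewer genes are named where they would repeat.

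The alternatives were thresholds of 0.01 and of a 2-fold change, no filter and a stricter filter (60th percentile, 6.18), quantile normalization among the arrays of a fit, centring of each array on its median, the mean of a gene's probe sets, an intensity trend with a robust prior, an unmoderated test, array weights, only the compared groups or all arrays in the fit, the replicate number as a block, each array left out in turn, and 2 arrays of 1-week Npc1+/+ mice left out together. An alternative that drops probe sets with shared sequence by their suffix could not be made, since this array's identifiers carry none.

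The procedure was tested on simulated data, with 200 genes changed by known amounts. At a log2 change of 1 it recovered 97.0% of changed genes in the 1-week contrast, 98.5% in the averaged one, 89.6% in the test of variation between ages, 97.0% in the oligo contrast and 98.5% in the fasting contrast. At a log2 change of 0.5 these shares were 80.6%, 100%, 35.8%, 74.6% and 89.6%. It called 16 of 16 shifted lists and 0 of 320 unchanged ones. The simulated genes varied independently of one another, so these list counts do not show how the tests behave on lists whose genes vary together.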

Results

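Liver RNA of 78 female mice was measured on an Affymetrix mouse array, 1 array per mouse and 35556 probe sets per array. The age series held 12 groups of 4 mice: Npc1-/- mice of the BALB/cNctr-Npc1m1N/J line and their Npc1+/+ littermates, taken every other week from 1 to 11 weeks of age. Npc1 encodes the late endosomal and lysosomal protein that carries cholesterol out of these compartments, and mice without it are a model of Niemann-Pick disease type C. The labels call the 1-week and 3-week mice pre-symptomatic and the older ones post-symptomatic. The second set held 6 groups of 5 BALB/cJ mice at 12 weeks: untreated, fasted overnight, and given for 4 weeks a control or an Npc1 antisense oligonucleotide (oligo), each with or without N-acetyl-cysteine (NAC), an antioxidant. Array medians ran from 5.35 to 5.65 on the log2 scale, and each array correlated with the others of its group at a mean Pearson r of 0.980 to 0.995 across genes. The number of mice per group limits the precision of every comparison. Unless another unit is given, values after gene names are log2 fold changes ± SE, over 4 mice per genotype and age or 5 mice per 12-week group.

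Npc1 mRNA was lower in Npc1-/- liver at every age and lower still under the Npc1 oligo. In Npc1+/+ mice its level was 9.26 ± 0.32 (SD, n = 4) at 1 week, 9.77 ± 0.06 at 3 weeks, 9.95 ± 0.33 at 7 weeks, 10.09 ± 0.17 at 9 weeks and 10.27 ± 0.25 at 11 weeks, and at 5 weeks the values ran from 9.63 to 10.25. In Npc1-/- mice it was, from the youngest to the oldest, 8.10 ± 0.13, 8.66 ± 0.10, 8.64 ± 0.30, 8.78 ± 0.31, 8.37 ± 0.08 and 8.71 ± 0.25, and at each age every Npc1-/- mouse lay below every Npc1+/+ mouse. The difference was -1.16 ± 0.16 at 1 week (adjusted p = 1.96e-06), -1.11 ± 0.16 at 3 weeks, -1.36 ± 0.16 at 5 weeks, -1.17 ± 0.16 at 7 weeks, -1.72 ± 0.16 at 9 weeks and -1.56 ± 0.16 at 11 weeks. In the 12-week set the level of Npc1 was 10.50 ± 0.12 in untreated and 10.61 ± 0.09 in fasted mice (0.11 ± 0.15, adjusted p = 0.914). It was 10.22 ± 0.14 (SD, n = 5) with the control oligo and 7.25 ± 0.22 with the Npc1 oligo, a difference of -2.97 ± 0.15 (adjusted p = 7.83e-15), and 9.19 ± 0.46 against 7.11 ± 0.31 in the groups given NAC (-2.08 ± 0.15). With the control oligo, NAC itself went with lower Npc1 (-1.03 ± 0.15, adjusted p = 6.05e-05), while with the Npc1 oligo the difference was -0.15 ± 0.15 (adjusted p = 0.645). Where the array's Npc1 probes lie relative to the mutation is not known here.

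**Figure D1:**
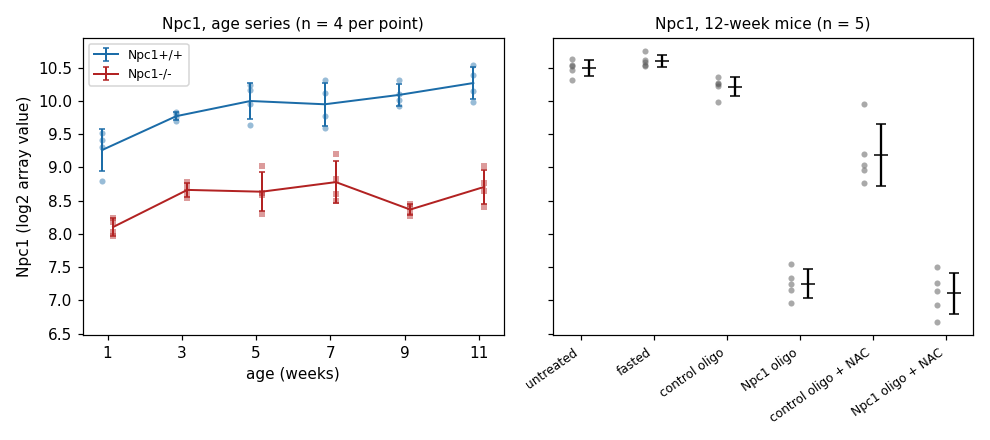
Npc1 mRNA level (log2 expression, vertical axis) by age in weeks for Npc1-/- and Npc1+/+ mice (left, n = 4 per group) and in the 6 groups of 12-week mice (right, n = 5 per group). Points are mice and error bars are the mean ± SD, so that the gap of -1.16 ± 0.16 at 1 week and of -2.97 ± 0.15 (SE) under the oligo can be read against the spread between mice.

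At 1 week the livers of Npc1-/- pups already expressed more of the genes for making cholesterol. Sqle, which encodes squalene epoxidase, rose by 1.90 ± 0.36, and Lss (1.59 ± 0.26), Idi1 (1.53 ± 0.29) and Fdps (1.42 ± 0.26) rose with it. Of the 20 measured genes of cholesterol synthesis and uptake 12 rose and 0 fell, 17 rising adjusted over the list alone. For the cholesterol list the median change was 0.76 (adjusted p = 2.24e-19, and adjusted p = 0.094 with an estimated correlation). Hepatocyte cytochrome P450s that metabolise drugs and steroids were lower: 10 of 18 fell, 12 adjusted over the list alone, led by Cyp2c50 (-1.83 ± 0.14) and Cyp2c54 (-1.52 ± 0.23). For the cytochrome P450 list the median change was -0.40 (adjusted p = 8.77e-18, and adjusted p = 0.0002 with an estimated correlation). Markers of resident Kupffer cells, the macrophages settled in the liver, fell in 3 of 8 genes (4 lower and 1 higher adjusted over the list alone), among them the haemoglobin scavenger receptor gene Cd163 (-1.58 ± 0.18) and the scavenger receptor gene Marco (-1.03 ± 0.11). For the Kupffer cell list the median change was -0.38 (adjusted p = 3.03e-06, and adjusted p = 0.0284 with an estimated correlation). Of 41 lysosomal genes 9 rose and 1 fell (15 and 1 adjusted over the list alone), with Hexa (0.96 ± 0.09), Ctsz (0.93 ± 0.08) and Npc2 (0.53 ± 0.08). For the lysosome list the median change was 0.13 (adjusted p = 5.66e-09, and adjusted p = 0.202 with an estimated correlation). The largest changes among all genes were those of Bex2 (3.04 ± 0.16) and of the lectin gene Cd209f (-2.89 ± 0.17), followed among lower genes by A2m (-2.84 ± 0.14), which encodes a plasma protease inhibitor. The 7 skeletal muscle genes tested, of 12 on the array, had a median change of 0.94, with 0 past the threshold over all genes and 7 adjusted over the list alone (adjusted p = 0.000148, adjusted p = 0.31 with an estimated correlation, and 0.707 without Npc1-/- mouse 3). The mean level of the 12 was 8.82 in Npc1-/- mouse 3 against 5.25 to 5.44 in the other 3 Npc1-/- pups. In all, limma placed 719 of 12638 genes past an adjusted p of 0.05, 368 higher and 351 lower, and of 39 gene lists 19 passed, 2 of them also with an estimated correlation. This count fell to 439 without Npc1-/- mouse 3, 288 higher and 151 lower, with 7 of the 19 lists no longer passing, none of them described above but the muscle genes. It fell to 396 without Npc1+/+ mouse 3 and to 430 without Npc1+/+ mouse 4, and was 223 without Npc1+/+ mice 3 and 4, whose original names are numbered apart from those of the other pups.

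At 3 weeks genes of lipid-laden macrophages set the livers of Npc1-/- mice apart. Gpnmb, a transmembrane glycoprotein gene of such macrophages, rose by 3.75 ± 0.16 and the macrophage elastase gene Mmp12 by 3.09 ± 0.19. In Npc1+/+ liver the mean level of Gpnmb was 5.14 to 5.43 at the 6 ages, below the median of all values (5.54), so that its changes with genotype, here and below, are lower bounds if that signal is background. Of that list, 13 of the 15 measured genes rose, 14 adjusted over the list alone. For the lipid-laden list the median change was 0.94 (adjusted p = 1.68e-22, and adjusted p = 0.000113 with an estimated correlation). General macrophage genes rose in 14 of 22 cases (17 adjusted over the list alone), with Lyz2 (1.86 ± 0.16). For the macrophage list the median change was 0.42 (adjusted p = 1.05e-16, and adjusted p = 0.0079 with an estimated correlation). Lysosomal genes rose in 27 of 41 (29 higher and 1 lower adjusted over the list alone), with Cd63 (2.51 ± 0.27) and Hexa (1.34 ± 0.09). Across the lysosome list the median was 0.31 (adjusted p = 1.52e-18, and adjusted p = 0.0363 with an estimated correlation). Cholesterol synthesis and uptake was higher at this age too, 16 of 20 genes rising and 1 falling (17 and 1 adjusted over the list alone), with Sqle (3.17 ± 0.36), Idi1 (1.87 ± 0.29) and Msmo1 (1.63 ± 0.29). Across the cholesterol list the median was 0.91 (adjusted p = 2.33e-12, and adjusted p = 0.178 with an estimated correlation). Among hepatocyte genes 11 of 18 cytochrome P450s fell (14 adjusted over the list alone), with Cyp2c38 (-2.41 ± 0.25). Across the cytochrome P450 list the median was -0.70 (adjusted p = 1.04e-15, and adjusted p = 0.000317 with an estimated correlation). Erythroid genes rose in 8 of 14 cases and fell in 1 (9 and 1 adjusted over the list alone), with Slc4a1 (1.23 ± 0.21) higher and Car1 (-1.01 ± 0.16) lower. For the erythroid list the median change was 0.48 (adjusted p = 5.87e-05, and adjusted p = 0.178 with an estimated correlation). Genes of fetal and imprinted expression rose in 5 of 12, 5 adjusted over the list alone, with Gpc3 (1.58 ± 0.24) and Igf2bp3 (0.85 ± 0.15). For the fetal and imprinted liver list the median change was 0.24 (adjusted p = 0.0014, and adjusted p = 0.0862 with an estimated correlation). Of 13 genes known as male-biased 6 fell (8 adjusted over the list alone), among them the major urinary protein gene Mup3 (-4.04 ± 0.33) and the fatty acid elongase gene Elovl3 (-1.72 ± 0.40), in mice that were all female. For the male-biased list the median change was -0.66 (adjusted p = 1.22e-06, and adjusted p = 0.0363 with an estimated correlation). Of 15 pancreas genes on the array 11 were tested and 11 fell (11 adjusted over the list alone), among them Cpb1 (-2.65 ± 0.70) and Try5 (-2.50 ± 0.66). The mean of the 15 was 8.13 in Npc1+/+ mouse 1 and 8.10 in mouse 2 against 4.76 to 5.03 in the other 6 mice. For the pancreas list the median change was -2.10 (adjusted p = 1.98e-08, and adjusted p = 0.178 with an estimated correlation). The count of genes past the threshold was 1989, 1125 higher and 864 lower, with 21 lists past it (5 with an estimated correlation), and was 1015 without both of these Npc1+/+ mice, a choice made after the data were seen. Without them the pancreas, resident Kupffer cell and ER stress lists no longer passed (adjusted p = 0.491, 0.109 and 0.0884), the glycolysis list did (0.00761), and 25 of 85 named genes tested so lost their call, of those named here only Cpb1 and Try5. Cpb1 was -0.24 ± 0.58 without both (adjusted p = 0.878), and its adjusted p ran from 0.000292 to 0.0737 when 1 mouse at a time was left out, 0.0720 without Npc1+/+ mouse 1 and 0.0737 without mouse 2. For Try5 these values were 0.0741 and 0.0753, in a range that began at 0.000464.

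At 5 weeks macrophage and lysosome genes were among the highest in Npc1-/- liver. Gpnmb (5.16 ± 0.16), Mmp12 (4.19 ± 0.19), Clec7a (3.69 ± 0.18) and Lilr4b (3.05 ± 0.18) rose, Clec7a encoding a receptor for fungal glucans on myeloid cells. Of the 15 genes of lipid-laden macrophages 14 rose, 14 adjusted over the list alone. Across the lipid-laden list the median was 1.39 (adjusted p = 5.45e-39, and adjusted p = 5.12e-07 with an estimated correlation). The general macrophage list had 14 of 22 genes higher, 19 adjusted over the list alone. Across the macrophage list the median was 0.68 (adjusted p = 4.9e-26, and adjusted p = 0.000666 with an estimated correlation). In the lysosome list the higher genes were 26 of 41, 31 adjusted over the list alone, with Cd63 (1.94 ± 0.27) and the cathepsin gene Ctsd (1.13 ± 0.09). The lysosome list had a median change of 0.50 (adjusted p = 4.9e-26, and adjusted p = 0.00997 with an estimated correlation). Resident Kupffer cell genes went the other way in 5 of 8 cases and up in 1, the same numbers adjusted over the list alone, with Cd163 (-2.73 ± 0.18) and Clec4f (-0.95 ± 0.13) lower. Across the Kupffer cell list the median was -0.47 (adjusted p = 4.28e-06, and adjusted p = 0.0152 with an estimated correlation). Cholesterol synthesis and uptake rose in 14 of 20 genes, 18 adjusted over the list alone, with Sqle (1.93 ± 0.36) and Hmgcs1 (1.31 ± 0.27), the latter the synthase that precedes HMG-CoA reductase. The cholesterol list had a median change of 0.92 (adjusted p = 6.08e-10, and adjusted p = 0.166 with an estimated correlation). Among the lowest genes were the organic anion transporter gene Slco1a1 (-4.15 ± 0.32), the carboxylesterase gene Ces3b (-3.56 ± 0.36) and the sulfotransferase gene Sult3a1 (-3.23 ± 0.25). In the male-biased list 9 of 13 genes fell, 9 adjusted over the list alone. Across the male-biased list the median was -0.60 (adjusted p = 4.56e-10, and adjusted p = 0.00541 with an estimated correlation). In all 1588 genes passed, 1224 higher and 364 lower, and 24 lists, 5 of them also with an estimated correlation.

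At 7 weeks every measured gene of the lipid-laden macrophage list was higher in Npc1-/- liver, together with most genes of the fibrosis list. Gpnmb (6.59 ± 0.16), Mmp12 (5.06 ± 0.19) and the lysosomal membrane protein gene Gpr137b (4.15 ± 0.18) led. The lipid-laden list rose in 15 of 15 genes, 15 adjusted over the list alone. The lipid-laden list had a median change of 1.72 (adjusted p = 1.28e-33, and adjusted p = 2.51e-06 with an estimated correlation). The macrophage list rose in 21 of 22, 22 adjusted over the list alone. The macrophage list had a median change of 1.08 (adjusted p = 1.88e-31, and adjusted p = 0.000152 with an estimated correlation). Lysosomal genes rose in 32 of 41 with 1 lower, 32 and 3 adjusted over the list alone. For the lysosome list the median change was 0.49 (adjusted p = 3.13e-21, and adjusted p = 0.0212 with an estimated correlation). Of 21 stellate cell and fibrosis genes 14 rose, 15 adjusted over the list alone, with Vim (2.11 ± 0.11) and the collagen gene Col1a1 (0.90 ± 0.14). For the fibrosis list the median change was 0.43 (adjusted p = 1.35e-06, and adjusted p = 0.0426 with an estimated correlation). Interferon response genes rose in 14 of 20 cases, 17 adjusted over the list alone, with Usp18 (2.13 ± 0.21). For the interferon list the median change was 0.79 (adjusted p = 4.41e-08, and adjusted p = 0.147 with an estimated correlation). On the hepatocyte side 11 of 20 genes of bile acid synthesis and transport fell, 11 adjusted over the list alone, with Slco1a1 (-5.52 ± 0.32) and the oxysterol hydroxylase gene Cyp7b1 (-1.76 ± 0.18). For the bile acid list the median change was -0.48 (adjusted p = 7.08e-06, and adjusted p = 0.0336 with an estimated correlation). Likewise 12 of 18 cytochrome P450s fell, 12 adjusted over the list alone, with Cyp2b10 (-1.99 ± 0.47). The cytochrome P450 list had a median change of -0.53 (adjusted p = 1.07e-07, and adjusted p = 0.017 with an estimated correlation). Immediate early genes, which respond within minutes to stress and handling, rose in 7 of 13 cases, 7 adjusted over the list alone, with Jun (1.66 ± 0.22) and Klf6 (1.57 ± 0.18). For the immediate early list the median change was 0.45 (adjusted p = 0.00302, and adjusted p = 0.151 with an estimated correlation). The count was 3195 genes, 1806 higher and 1389 lower, and 21 lists passed, 8 of them also with an estimated correlation.

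At 9 weeks all 22 macrophage genes tested, of 23 on the array, were higher and endothelial genes lower. The macrophage list rose in 22 of 22 genes, 22 adjusted over the list alone, with Ctss (3.70 ± 0.14) and Cd68 (3.68 ± 0.12). For the macrophage list the median change was 1.36 (adjusted p = 7.21e-30, and adjusted p = 0.00023 with an estimated correlation). The lipid-laden list rose in 15 of 15, 15 adjusted over the list alone, with Gpnmb (6.72 ± 0.16) and Itgax (4.25 ± 0.16). For the lipid-laden list the median change was 2.14 (adjusted p = 1.93e-30, and adjusted p = 6.89e-06 with an estimated correlation). Lysosomal genes rose in 31 of 41 cases and fell in 1 (32 and 2 adjusted over the list alone), with Ctsk (2.29 ± 0.15) and Gla (1.95 ± 0.13). Across the lysosome list the median was 0.69 (adjusted p = 3.91e-21, and adjusted p = 0.0361 with an estimated correlation). Markers of sinusoidal endothelial cells, which line the liver capillaries, fell in 12 of 14 cases (13 lower and 1 higher adjusted over the list alone), with the VEGF receptor gene Kdr (-0.84 ± 0.12) and the cadherin gene Cdh5 (-0.75 ± 0.09). For the endothelial list the median change was -0.49 (adjusted p = 6.59e-07, and adjusted p = 0.0767 with an estimated correlation). Genes of glycolysis and glucose use rose in 5 of 11 cases, 5 adjusted over the list alone. For the glycolysis list the median change was 0.25 (adjusted p = 0.000567, and adjusted p = 0.0412 with an estimated correlation). Among these were Hk3 (2.07 ± 0.10) and Pkm (1.35 ± 0.10), hexokinase and pyruvate kinase forms of blood cells and growing cells rather than of hepatocytes. Genes of p53 and growth arrest rose in 7 of 11 cases, 8 adjusted over the list alone, with Gadd45b (2.03 ± 0.32) and Gadd45a (1.44 ± 0.22). For the growth arrest list the median change was 0.48 (adjusted p = 0.00174, and adjusted p = 0.0412 with an estimated correlation). The count was 4190 genes, 2225 higher and 1965 lower, and 18 lists passed, 5 of them also with an estimated correlation.

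At 11 weeks genes of macrophages were higher in Npc1-/- liver and genes of lipid synthesis lower. Gpnmb (7.12 ± 0.16), against a low level of 5.22 in Npc1+/+ liver, and the lipoprotein lipase gene Lpl (4.66 ± 0.21) rose with 15 of 15 genes of lipid-laden macrophages, 15 adjusted over the list alone. Across the lipid-laden list the median was 2.29 (adjusted p = 6.38e-26, and adjusted p = 3.57e-05 with an estimated correlation). The macrophage list rose in 22 of 22 genes, 22 adjusted over the list alone. Across the macrophage list the median was 1.57 (adjusted p = 3.56e-26, and adjusted p = 0.000578 with an estimated correlation). Lysosomal genes rose in 31 of 41 with 1 lower (32 and 2 adjusted over the list alone), with Ctsk (3.60 ± 0.15). The lysosome list had a median change of 0.61 (adjusted p = 2.73e-19, and adjusted p = 0.0402 with an estimated correlation). Fatty acid synthesis genes fell in 14 of 17 cases, 14 adjusted over the list alone, with Thrsp (-3.11 ± 0.53) and Elovl5 (-1.75 ± 0.16). For the fatty acid synthesis list the median change was -1.08 (adjusted p = 9.56e-07, and adjusted p = 0.105 with an estimated correlation). Genes of fatty acid oxidation under PPAR-alpha fell in 21 of 27 cases and rose in 1 (21 and 2 adjusted over the list alone), with Acot1 (-1.83 ± 0.39) and Vnn1 (-1.79 ± 0.32). For the PPAR-alpha list the median change was -0.62 (adjusted p = 2.55e-06, and adjusted p = 0.244 with an estimated correlation). Cholesterol synthesis and uptake, higher at the young ages, now had 8 of 20 genes lower, 8 adjusted over the list alone, with Sc5d (-1.48 ± 0.22) and Tm7sf2 (-1.34 ± 0.17), while Sqle was at 0.73 ± 0.36 (adjusted p = 0.11). For the cholesterol list the median change was -0.43 (adjusted p = 0.0149, and adjusted p = 0.691 with an estimated correlation). That list's call ended when Npc1-/- mouse 4 or Npc1+/+ mouse 4 was left out (adjusted p = 0.0520 and 0.0557, in a range from 0.00136) and after quantile normalization (adjusted p = 0.0576). The male-biased list fell in 9 of 13 genes, 9 adjusted over the list alone, with Mup3 (-6.24 ± 0.33). The male-biased list had a median change of -0.93 (adjusted p = 1.46e-06, and adjusted p = 0.0402 with an estimated correlation). The estrogen sulfotransferase gene Sult1e1 (5.09 ± 0.56) rose. The count was 4973 genes, 2378 higher and 2595 lower, and 21 lists passed, 4 of them also with an estimated correlation.

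Averaged over the 6 ages, macrophage and lysosome genes were higher and drug-metabolising cytochrome P450 genes lower in Npc1-/- liver. Ranked by fitted size among genes with the same sign at all ages, the highest were Gpnmb (5.02 ± 0.07), Mmp12 (3.73 ± 0.08), Clec7a (3.60 ± 0.07), Gpr137b (3.09 ± 0.07), Lgals3 (2.67 ± 0.06), Itgax (2.66 ± 0.07), Cd68 (2.64 ± 0.05) and Lyz2 (2.57 ± 0.07), and the lowest were Slco1a1 (-3.55 ± 0.13), Ces3b (-3.47 ± 0.15), Sult3a1 (-3.34 ± 0.10), Cd163 (-2.62 ± 0.07), Sult2a8 (-2.50 ± 0.10) and the organic anion transporter gene Slc22a7 (-2.15 ± 0.07). The value of Gpnmb, low in Npc1+/+ liver at every age, is again a lower bound if that signal is background. All 15 of 15 lipid-laden macrophage genes rose, 15 adjusted over the list alone. The lipid-laden list had a median change of 1.34 (adjusted p = 2.87e-23, and adjusted p = 8.45e-05 with an estimated correlation). The list mean of every Npc1-/- mouse lay above that of every Npc1+/+ mouse at each age. In the general macrophage list 22 of 22 genes were higher, 22 adjusted over the list alone. The macrophage list had a median change of 0.83 (adjusted p = 5.92e-23, and adjusted p = 0.00159 with an estimated correlation). Lysosomal genes rose in 34 of 41 cases and fell in 2, with the same numbers adjusted over the list alone. For the lysosome list the median change was 0.48 (adjusted p = 2.42e-20, and adjusted p = 0.0256 with an estimated correlation). Cytochrome P450s fell in 15 of 18 cases, 15 adjusted over the list alone, with Cyp2c54 (-1.60 ± 0.09) and Cyp4f14 (-1.38 ± 0.06). For the cytochrome P450 list the median change was -0.51 (adjusted p = 6.56e-09, and adjusted p = 0.00937 with an estimated correlation). Their mean was lower in every Npc1-/- mouse than in any Npc1+/+ mouse of its age. Resident Kupffer cell genes fell in 6 of 8 cases and rose in 1, equally so adjusted over the list alone, with Clec4f (-1.12 ± 0.05) and Folr2 (-0.94 ± 0.04) lower. The Kupffer cell list had a median change of -0.54 (adjusted p = 0.00045, and adjusted p = 0.065 with an estimated correlation). Interferon response genes rose in 18 of 20 cases, 18 adjusted over the list alone. Across the interferon list the median was 0.45 (adjusted p = 1.91e-06, and adjusted p = 0.211 with an estimated correlation). The count was 6642 of 12638 genes, or 52.6%, with 3282 higher and 3360 lower. Of 39 lists 22 passed, 14 up and 8 down, and 6 of them also passed with an estimated correlation.

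**Figure D2:**
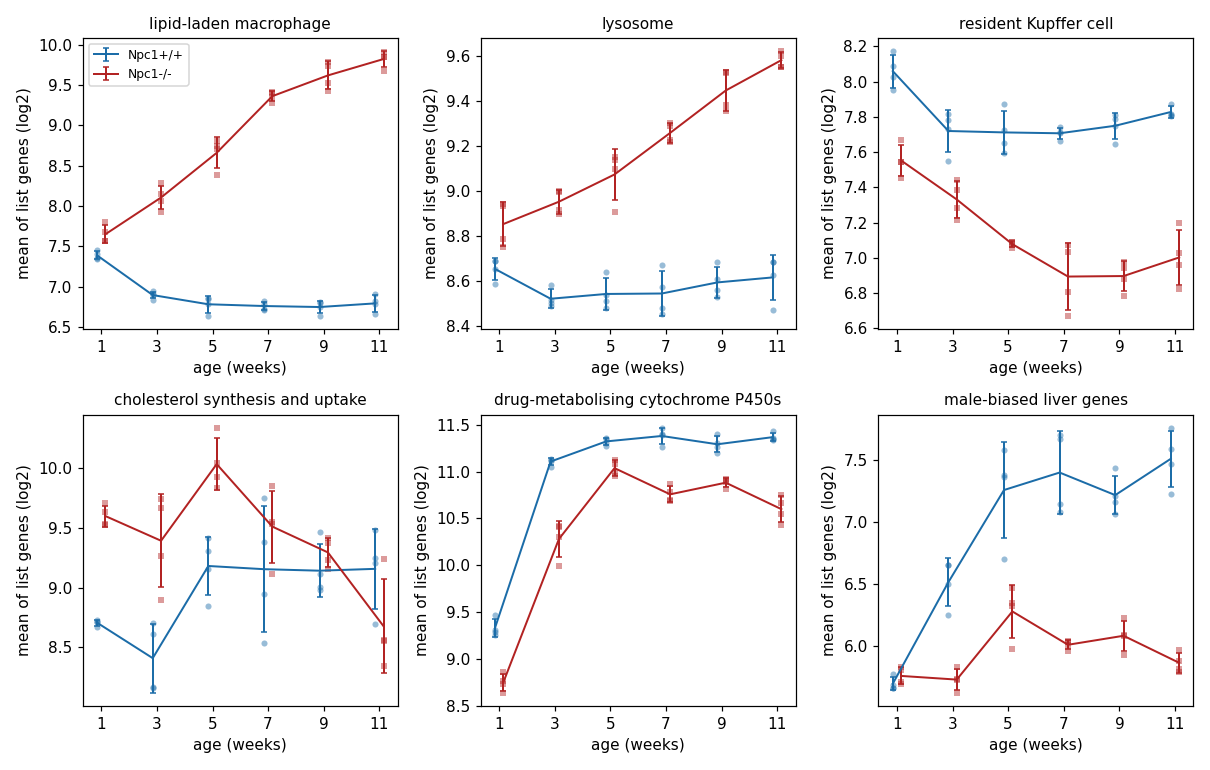
Mean log2 expression of 6 gene lists (vertical axes) by age in weeks, for Npc1-/- and Npc1+/+ mice. Points are mice, lines and error bars are the mean ± SD of 4 mice per group, and the lipid-laden macrophage mean ran from 7.65 at 1 week to 9.82 at 11 weeks in Npc1-/- mice, against 7.39 and 6.79 in Npc1+/+ mice.

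The size of the genotype effect changed with age for 3501 genes (moderated F test over 5 contrasts), and a linear trend with age passed for 3647, 1879 of them moving up and 1768 down. Per week of age the difference between the genotypes grew by 0.60 ± 0.02 for Gpnmb, 0.53 ± 0.02 for Lpl, 0.51 ± 0.02 for the interleukin-7 receptor gene Il7r and 0.48 ± 0.02 for Anxa1, and it changed by -0.69 ± 0.03 for Sult3a1, -0.61 ± 0.04 for Slco1a1 and -0.49 ± 0.04 for Mup3 (log2 per week). Slopes were up for 15 of 15 lipid-laden macrophage genes, 15 adjusted over the list alone (median slope 0.23, adjusted p = 2.08e-27, and adjusted p = 2.12e-05 with an estimated correlation), and for 14 of 14 neutrophil genes, 14 adjusted over the list alone, with Lcn2 (0.30 ± 0.04) (median slope 0.09, adjusted p = 2.47e-08, and adjusted p = 0.0464 with an estimated correlation). Slopes were down for all 20 of 20 genes of cholesterol synthesis and uptake, 20 adjusted over the list alone, with Idi1 (-0.24 ± 0.03) and Cyp51 (-0.19 ± 0.04) (median slope -0.14, adjusted p = 3.84e-12, and adjusted p = 0.152 with an estimated correlation). The cholesterol list mean of Npc1-/- liver was 9.60 at 1 week and 8.68 at 11 weeks, against 8.71 and 9.16 in Npc1+/+ liver. The genotype difference in Npc1 itself did not pass the F test between the ages (adjusted p = 0.118).

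In Npc1+/+ mice themselves, 6730 of 12638 genes (53.3%) changed between the ages. From 1 to 11 weeks, on the log2 scale (4 mice per age), the major urinary protein gene Mup3 differed by 7.47, the cytochrome P450 genes Cyp2c39 and Cyp2c38 by 6.55 and 6.54, and the iron hormone gene Hamp by 6.35, all higher at 11 weeks. The fetal plasma protein gene Afp differed by -7.12, the fetal growth factor gene Igf2 by -6.16, A2m by -5.30 and the neutrophil granule gene Ngp by -5.24.

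Lowering Npc1 with the oligo in adult mice asks whether the loss of Npc1 begun at 8 weeks changes the liver in the same way as its loss from birth. With the Npc1 oligo Mmp12 (3.82 ± 0.40), Gpnmb (3.07 ± 0.43), Clec7a (2.66 ± 0.29), Lgals3 (1.79 ± 0.26) and Itgax (1.67 ± 0.29) rose, with Apoa4 (1.70 ± 0.16) and the lipid droplet gene Cidec (1.63 ± 0.18). The steroid dehydrogenase gene Hsd3b5 (-3.02 ± 0.27), the lipogenic gene Thrsp (-2.68 ± 0.27), Slc22a7 (-2.53 ± 0.13) and the lipogenic transcription factor gene Srebf1 (-1.85 ± 0.12) fell. Lipid-laden macrophage genes rose in 12 of 15 cases, 13 adjusted over the list alone. For the lipid-laden list the median change was 0.80 (adjusted p = 1.41e-10, and adjusted p = 0.201 with an estimated correlation). Lysosomal genes rose in 26 of 40, 29 adjusted over the list alone, with Cd63 (1.43 ± 0.27) and Ctsd (0.89 ± 0.10). Across the lysosome list the median was 0.32 (adjusted p = 2.21e-15, and adjusted p = 0.201 with an estimated correlation). Macrophage genes rose in 13 of 20 cases, 14 adjusted over the list alone, with Ctss (1.48 ± 0.21). For the macrophage list the median change was 0.66 (adjusted p = 1.17e-09, and adjusted p = 0.326 with an estimated correlation). Genes of cholesterol synthesis and uptake fell in 16 of 20 cases, 18 adjusted over the list alone, with Fdps (-1.18 ± 0.18) and Stard4 (-1.16 ± 0.12). Across the cholesterol list the median was -0.60 (adjusted p = 2.41e-14, and adjusted p = 0.201 with an estimated correlation). Cytochrome P450s fell in 12 of 18 cases, 12 adjusted over the list alone, with Cyp2c54 (-1.20 ± 0.16). Across the cytochrome P450 list the median was -0.31 (adjusted p = 1.41e-10, and adjusted p = 0.201 with an estimated correlation). Interferon response genes rose in 15 of 20 cases, 16 adjusted over the list alone, with Usp18 (1.24 ± 0.27). The interferon list had a median change of 0.65 (adjusted p = 9.4e-07, and adjusted p = 0.464 with an estimated correlation). Heat shock genes rose in 7 of 10, 7 adjusted over the list alone, with Hsph1 (1.11 ± 0.15). For the heat shock list the median change was 0.48 (adjusted p = 3.97e-05, and adjusted p = 0.244 with an estimated correlation). In every mouse given the Npc1 oligo the means of the lipid-laden macrophage and lysosome lists lay above, and those of the cholesterol and cytochrome P450 lists below, the means of every control oligo mouse. The resident Kupffer cell list did not pass (adjusted p = 0.6, median change 0.03). In all 2688 of 11900 genes passed, 1750 higher and 938 lower. None of the 12 lists past the threshold held with an estimated correlation.

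With NAC given to both groups, the Npc1 oligo raised genes of macrophages and of fatty acid oxidation and lowered those of cholesterol synthesis. Mmp12 (4.02 ± 0.40), Gpnmb (3.37 ± 0.43), Clec7a (2.61 ± 0.29) and Cidec (2.15 ± 0.18) rose, and 14 of 15 lipid-laden macrophage genes rose, 14 adjusted over the list alone. Across the lipid-laden list the median was 0.76 (adjusted p = 2.52e-11, and adjusted p = 0.21 with an estimated correlation). Fatty acid oxidation genes under PPAR-alpha rose in 21 of 27 cases and fell in 1 (24 and 1 adjusted over the list alone), with Cyp4a10 (2.32 ± 0.22) and Acot2 (1.79 ± 0.15). Across the PPAR-alpha list the median was 0.47 (adjusted p = 2.24e-18, and adjusted p = 0.121 with an estimated correlation). This rise was not confined to NAC. Without NAC the list mean was 10.235 to 10.417 in Npc1 oligo mice and 9.876 to 10.199 in control oligo mice. Cholesterol synthesis and uptake genes fell in 19 of 20 cases, 19 adjusted over the list alone, with Idi1 (-1.56 ± 0.23) and Cyp51 (-1.50 ± 0.20). The cholesterol list had a median change of -0.86 (adjusted p = 2.24e-18, and adjusted p = 0.121 with an estimated correlation). Immediate early genes fell in 10 of 14 cases, 10 adjusted over the list alone, with Nr4a1 (-3.52 ± 0.57) and Dusp1 (-2.03 ± 0.23). Across the immediate early list the median was -0.98 (adjusted p = 1.33e-05, and adjusted p = 0.349 with an estimated correlation). The retinoic acid hydroxylase gene Cyp26a1 (-3.38 ± 0.28) fell as well. In mouse 3 of the group given the Npc1 oligo and NAC the level of Gpnmb was 6.32, against 9.61 to 9.78 in the others, and its lipid-laden macrophage mean was 7.42 against 8.65 to 8.93. Its array also had the lowest median (5.35) and upper quartile (7.12) of all 78 arrays. The count was 3058 genes, 1310 higher and 1748 lower (without that mouse 1828 higher and 1425 lower), and none of the 17 lists that passed did so with an estimated correlation. Across 11900 genes, which are not independent replicates, the oligo effects without and with NAC had a Pearson r of 0.640 and a Spearman rho of 0.462, and of the 1349 genes past the threshold in both, 1300 (96.4%) had the same direction.

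**Figure D3:**
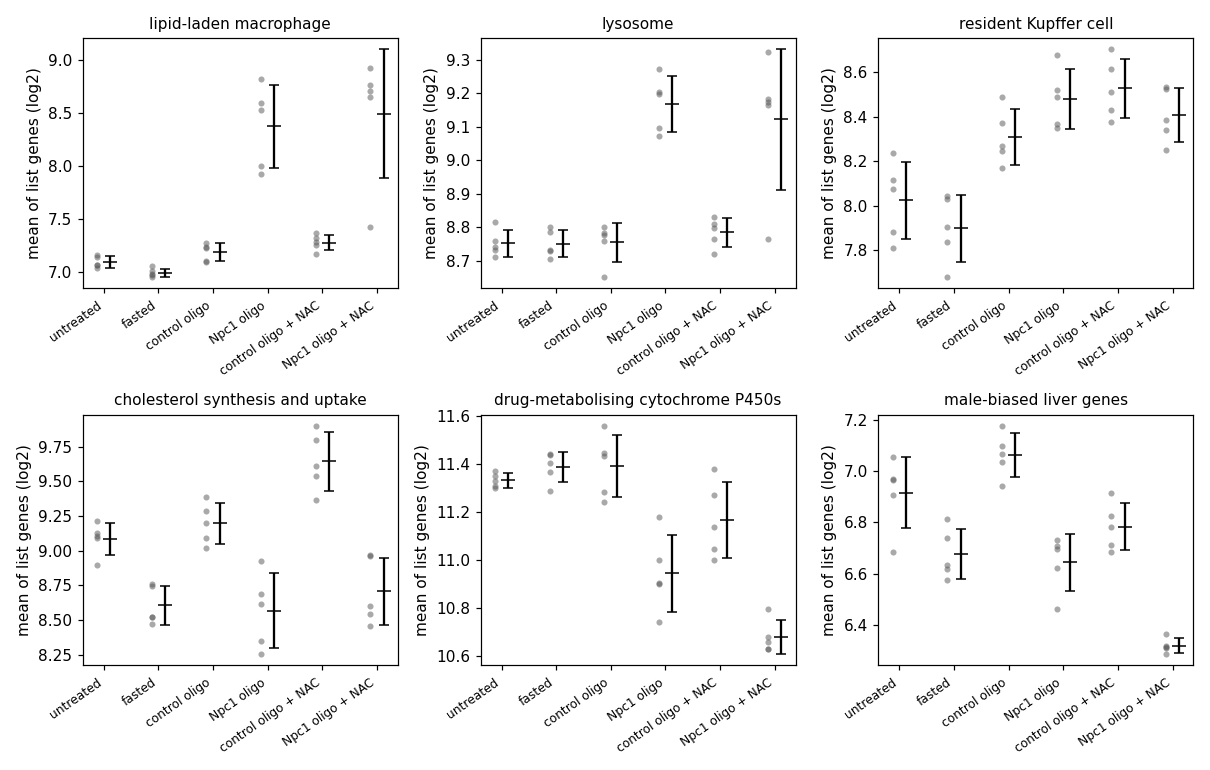
Mean log2 expression of 6 gene lists (vertical axes) in the 6 groups of 12-week mice. Points are mice, error bars are the mean ± SD of 5 mice per group, and the lipid-laden macrophage mean was 8.37 with the Npc1 oligo and 8.49 with the Npc1 oligo and NAC, against 7.19 and 7.27 in the matching control oligo groups.

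The genotype effect at 11 weeks and the oligo effect at 12 weeks went largely in the same direction among genes called in both. They differed in size and, for some lists, in direction. Across 11859 genes their Pearson r was 0.588 and their Spearman rho 0.407, with genes not being independent replicates. Of 1579 genes past the threshold in both, 1403 (88.9%) had the same direction: 813 were higher in both against 324 expected of independent lists, and 590 lower in both against 202. Tested as a difference of the 2 effects, Gpnmb (4.05 ± 0.47), Lpl (3.85 ± 0.27), Il7r (3.30 ± 0.39) and Ctsk (3.23 ± 0.20) were among the highest single genes. Lipid-laden macrophage genes had the larger change by genotype, 14 of 15 differing upwards, 15 adjusted over the list alone. The lipid-laden list had a median change of 1.67 (adjusted p = 1.74e-17, and adjusted p = 0.0229 with an estimated correlation). Resident Kupffer cell genes differed downwards in 5 of 8 cases and upwards in 2 (6 and 2 adjusted over the list alone), with Cd163 (-3.23 ± 0.25) and Clec4f (-2.33 ± 0.18). For the Kupffer cell list the median change was -0.92 (adjusted p = 0.000384, and adjusted p = 0.159 with an estimated correlation). The mean of this list was 7.00 in Npc1-/- against 7.83 in Npc1+/+ mice at 11 weeks. It was 8.48 with the Npc1 oligo against 8.31 with the control oligo. Fatty acid oxidation genes under PPAR-alpha differed downwards in 24 of 27 cases, 24 adjusted over the list alone, with Acot1 (-2.27 ± 0.47) and Vnn1 (-2.16 ± 0.44). The PPAR-alpha list had a median change of -0.87 (adjusted p = 1.85e-13, and adjusted p = 0.108 with an estimated correlation). Here the 2 effects were opposite in direction. The list mean was 9.54 in Npc1-/- against 10.20 in Npc1+/+ mice at 11 weeks, but 10.33 with the Npc1 oligo against 10.02 with the control oligo. Among single genes Mup3 (-5.88 ± 0.36), Sult3a1 (-5.77 ± 0.31) and Slco1a1 (-5.60 ± 0.38) differed most. The count was 3528 of 12748 genes, 1490 upwards and 2038 downwards, and 19 lists passed, 1 of them also with an estimated correlation. Age, duration, line and batch of animals differ between these sets.

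NAC in mice given the control oligo went with higher acute phase genes. The serum amyloid genes Saa1 (3.84 ± 0.69) and Saa3 (3.27 ± 0.46), Lcn2 (3.02 ± 0.41) and Orm2 (2.66 ± 0.35) rose, as did 14 of 23 acute phase and complement genes, 18 adjusted over the list alone. For the acute phase list the median change was 0.38 (adjusted p = 1.09e-13, and adjusted p = 0.231 with an estimated correlation). The control oligo group was uneven, with Saa1 at 10.25 and 10.49 in mice 1 and 4 and at 6.45 to 6.67 in the other 3, against 11.2 to 12.3 in the mice given NAC as well. Of 15 neutrophil genes on the array 5 passed the filter, and 5 of these 5 rose, 5 adjusted over the list alone. Genes could pass the filter through the very group in which they are high, so this share and the list test are partly set by it. For the neutrophil list the median change was 0.96 (adjusted p = 1.16e-06, and adjusted p = 0.103 with an estimated correlation). Sterol synthesis and uptake genes rose in 12 of 20 cases, 15 adjusted over the list alone, with Cyp51 (0.86 ± 0.20) and Nsdhl (0.73 ± 0.17). For the cholesterol list the median change was 0.48 (adjusted p = 7.07e-08, and adjusted p = 0.306 with an estimated correlation). Clock genes moved with NAC in both directions, 2 higher and 5 lower of 16 (3 and 8 adjusted over the list alone), with Dbp (-1.32 ± 0.23), Per3 (-0.99 ± 0.16) and Arntl (1.04 ± 0.18). For the clock list the median change was -0.22 (adjusted p = 0.0034, and adjusted p = 0.306 with an estimated correlation). Heat shock genes rose in 6 of 10 cases, 6 adjusted over the list alone, with Dnajb1 (1.06 ± 0.15) and Hspa1a (1.04 ± 0.19). Across the heat shock list the median was 0.46 (adjusted p = 5.42e-06, and adjusted p = 0.231 with an estimated correlation). In all 1012 genes passed, 725 higher and 287 lower, and 11 lists, 0 of them with an estimated correlation. This count was 587 without control oligo mouse 2, 562 without control oligo and NAC mouse 2, and 552 with only these 2 groups in the fit.

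Among mice given the Npc1 oligo, genes of immediate early response and of gluconeogenesis were lower in those given NAC as well. Nr4a1 (-2.36 ± 0.57), Dusp1 (-2.21 ± 0.23), Btg2 (-1.86 ± 0.36) and Fos (-1.63 ± 0.38) fell, and of 14 immediate early genes 6 fell, 11 adjusted over the list alone. The immediate early list had a median change of -0.82 (adjusted p = 5.44e-07, and adjusted p = 0.615 with an estimated correlation). Gluconeogenesis and fasting hormone genes fell in 8 of 11 cases and rose in 1, alike adjusted over the list alone, with Igfbp1 (-1.37 ± 0.30) and Ppargc1a (-1.14 ± 0.22). For the gluconeogenesis list the median change was -0.44 (adjusted p = 2.21e-07, and adjusted p = 0.126 with an estimated correlation). Orm2 (1.85 ± 0.35), Lcn2 (1.75 ± 0.41), Osgin1 (1.39 ± 0.20) and Acot3 (1.20 ± 0.22) rose, while the xenobiotic-induced Cyp2b10 (-1.56 ± 0.14) and Lpin1 (-1.53 ± 0.23) fell. The count was 851 genes, 343 higher and 508 lower, 545 without Npc1 oligo mouse 4 and 393 with only these 2 groups in the fit. The interaction of NAC and oligo, tested directly, passed for 575 genes, 137 upwards and 438 downwards. It was upwards for Acot3 (1.51 ± 0.31), Per3 (1.36 ± 0.22) and Acaa1b (0.99 ± 0.15) and for 9 of 27 fatty acid oxidation genes, 12 adjusted over the list alone. For the PPAR-alpha list the median change was 0.23 (adjusted p = 5.98e-11, and adjusted p = 0.322 with an estimated correlation). It was downwards for Dusp1 (-1.73 ± 0.33), Trp53inp1 (-1.75 ± 0.36) and Cyp26a1 (-1.76 ± 0.39) and for 8 of 18 genes of ER stress and the amino acid response, 13 adjusted over the list alone, with Pdia6 (-0.69 ± 0.12). For the ER stress list the median change was -0.44 (adjusted p = 1.24e-05, and adjusted p = 0.322 with an estimated correlation). For Npc1 it was 0.88 ± 0.21 (adjusted p = 0.0145, in a range of 0.000393 to 0.0594 over the alternatives, the highest with only the compared groups in the fit). The interaction count was 373 without control oligo mouse 2, 346 without control oligo and NAC mouse 2, 979 without control oligo and NAC mouse 3, 1037 without Npc1 oligo and NAC mouse 4, and 226 with only the compared groups in the fit.

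An overnight fast changed few genes, with fat oxidation genes among the higher and sterol synthesis genes among the lower. The fatty acid hydroxylase gene Cyp4a14 (1.12 ± 0.19), the redox regulator gene Txnip (1.08 ± 0.19), the lipoprotein receptor gene Vldlr (0.80 ± 0.14) and the glucose-6-phosphatase gene G6pc (0.64 ± 0.12) rose, and Hsd3b5 (-1.70 ± 0.27), Ces3b (-1.10 ± 0.20), Angptl8 (-0.95 ± 0.17) and Selenbp2 (-0.82 ± 0.15) fell. Of 20 genes of cholesterol synthesis and uptake 5 fell over all genes tested and 17 adjusted over the list alone. Across the cholesterol list the median was -0.39 (adjusted p = 1.46e-21, and adjusted p = 0.0673 with an estimated correlation). The list mean of every fasted mouse lay below that of every untreated mouse. Fatty acid oxidation genes under PPAR-alpha rose in 3 of 27 cases, 9 adjusted over the list alone. Across the PPAR-alpha list the median was 0.18 (adjusted p = 1.52e-18, and adjusted p = 0.0673 with an estimated correlation). Female-biased genes rose in 2 of 12, 6 adjusted over the list alone, with Cyp2b13 (0.53 ± 0.09). For the female-biased list the median change was 0.26 (adjusted p = 2.54e-12, and adjusted p = 0.00679 with an estimated correlation). In all 63 genes passed, 25 higher and 38 lower, and 10 lists, 1 of them also with an estimated correlation. The count was 26 without untreated mouse 4, 25 without fasted mouse 4 and 33 without fasted mouse 5, and it was 159 with only these 2 groups in the fit and 357 with array weights.

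The control oligo, set against no treatment, raised immediate early, gluconeogenic and acute phase genes. Igfbp1 (3.94 ± 0.30), the growth arrest gene Gadd45g (3.46 ± 0.26), Nr4a1 (3.35 ± 0.57), Dusp1 (2.87 ± 0.23), Jun (2.67 ± 0.32) and Fos (2.64 ± 0.38) rose, and 12 of 14 immediate early genes rose, 12 adjusted over the list alone. Their median change was 1.21 (adjusted p = 2.36e-15, and adjusted p = 0.104 with an estimated correlation). Gluconeogenesis and fasting hormone genes rose in 7 of 11 cases (8 higher and 1 lower adjusted over the list alone), with Ppargc1a (1.19 ± 0.22) and G6pc (0.98 ± 0.12). The list median was 0.46 (adjusted p = 7.24e-09, and adjusted p = 0.095 with an estimated correlation). Acute phase genes rose in 9 of 23 and fell in 1, equally so adjusted over the list alone, with Saa2 (2.73 ± 0.60). Across the acute phase list the median was 0.24 (adjusted p = 1.5e-07, and adjusted p = 0.311 with an estimated correlation). Mice 1 and 4 of the control oligo group stood apart in Saa1, at 10.25 and 10.49 against 6.45 to 6.67 in the other 3 and 5.22 to 5.88 in untreated mice. Macrophage genes rose in 10 of 20 cases, 13 adjusted over the list alone, with Cd14 (1.34 ± 0.30) and Cd68 (0.73 ± 0.20). Their median was 0.36 (adjusted p = 4.32e-09, and adjusted p = 0.311 with an estimated correlation). Fatty acid synthesis genes fell in 12 of 17 cases and rose in 1, with the same numbers adjusted over the list alone, Pklr (-1.12 ± 0.12) among them. The list median was -0.44 (adjusted p = 0.00012, and adjusted p = 0.311 with an estimated correlation). The lipid hormone gene Angptl8 (-1.56 ± 0.17) fell. The count was 3132 genes, 601 higher and 2531 lower, with 15 lists past the threshold and 0 with an estimated correlation, and Npc1 differed by -0.28 ± 0.15 (adjusted p = 0.171, in a range of 0.0197 to 0.357 over the alternatives, the lowest with only these groups in the fit).

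**Figure D4:**
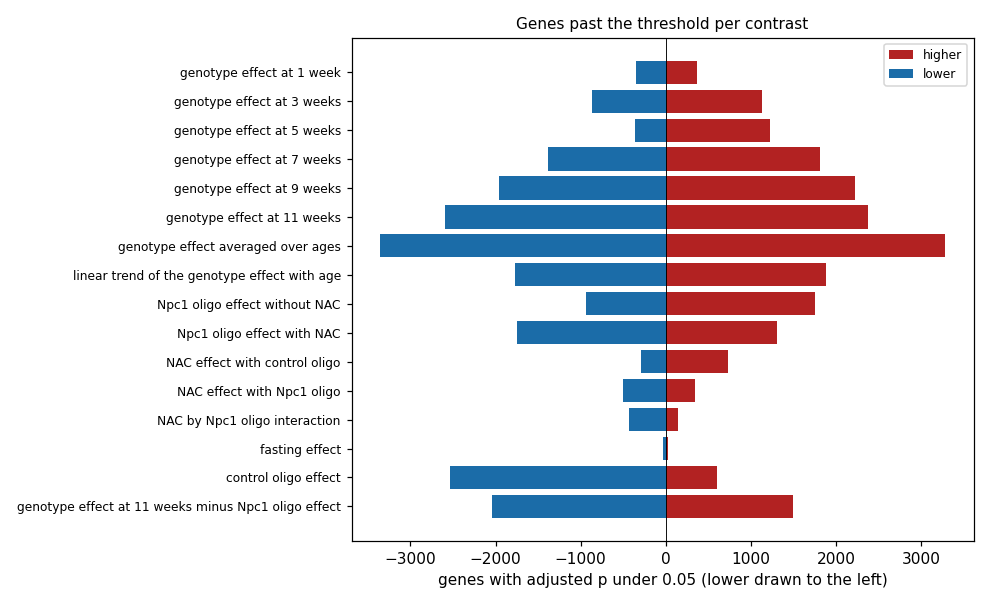
Number of genes past an adjusted p of 0.05 in each of 16 contrasts (horizontal axis, genes higher to the right and lower to the left of 0). The count ran from 63 for the overnight fast to 6642 for the genotype effect averaged over the ages, with 4 mice per group in the age series and 5 in the 12-week set.

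The balance of higher and lower genes in these counts depended on the scaling of the arrays, while no gene and no list described here changed direction under either scaling. Centring each array on its median lowered the share of higher genes from 51.2% to 44.2% at 1 week, from 56.6% to 41.9% at 3 weeks, from 77.1% to 65.0% at 5 weeks, from 56.5% to 37.4% at 7 weeks, from 53.1% to 36.3% at 9 weeks and from 47.8% to 33.0% at 11 weeks. For the mean over the ages the share went from 49.4% to 31.7%, for the slope from 51.5% to 37.4%, and for the difference between genotype and oligo effects from 42.2% to 25.4%. It moved the median of all genes tested at 11 weeks by -0.10, and for the difference between genotype and oligo effects by -0.12. Quantile normalization among the arrays of a fit raised the share of higher genes from 19.2% to 41.3% for the control oligo and from 23.8% to 49.1% for the interaction of NAC and oligo, and lowered it from 71.6% to 50.8% for NAC with the control oligo.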

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

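Of the tests below, those on feeding state, pancreatic tissue, RNA mixing and all counts of other splits were chosen only after the result was seen, while those on time of day were chosen before. Of 180 tests for a single outlying mouse (10 quantities in 18 groups) 19 passed, where chance alone gives about 1 in 20, or 9.

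Pancreas genes were lower in Npc1-/- than in Npc1+/+ livers at 3 weeks, with a median log2 change of -2.10. Without Npc1+/+ mice 1 and 2 the value was -0.13 (95% interval over genes -0.29 to 0.05), with 0 of 11 genes past the threshold. These mice were found by the mean of the same list, so leaving them out had to shrink the difference. Whether Npc1-/- liver expresses less of these genes is therefore not decided by it. Pancreatic tissue in the samples of mice 1 and 2 stays open as well. For 100% of the 11 genes the highest pair of values was in these mice, but for the same reason this count cannot decide it. Ctrb1 averaged 7.83 ± 2.44 (SD, n = 4) in the Npc1+/+ and 5.40 ± 0.38 in the Npc1-/- group. Outside these mice the list means at 3 weeks, 4.76 to 5.03, lay below the median of all values, 5.54. No biological explanation other than the genotype was tested.

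Cholesterol synthesis and uptake genes were higher in Npc1-/- mice at 3 weeks (median 0.91), lower at 11 weeks (-0.43) and lower under the Npc1 oligo (-0.60), and they also fell on fasting (-0.39). The 57 other genes called on fasting moved by 0.18 (-0.00 to 0.29) in the direction of a fast at 3 weeks, where -1.04 was needed. They moved by 0.30 (0.11 to 0.71) of a needed 0.49 at 11 weeks, and by 0.32 (0.23 to 0.52) of a needed 0.68 under the oligo. These genes were called in adult mice and may respond to genotype and oligo themselves. Ces3b, lower on fasting, was also lower in Npc1-/- liver. Feeding state therefore stays open in each of these comparisons. The PPAR-alpha list, with a median of 0.18 on fasting, was at -0.62 at 11 weeks, opposite to a fast, and at 0.24 under the oligo, but these genes may also respond to genotype and oligo themselves, so that they do not decide it. With components of the clock genes as covariates, 4, 9 and 14 genes of the list were past the threshold. For these genes time of day as the whole cause is argued against. The list medians in that fit were 0.67 (0.51 to 0.91), -0.64 (-0.98 to -0.46) and -0.52 (-0.81 to -0.32). These intervals are over genes and do not measure the spread between mice. At 3 weeks fewer genes passed than without the covariates, so time of day stays open for the rest of the list. A response of the liver to genotype, age and oligo stays open and was not tested further.

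Npc1 was lower by -1.03 in mice given the control oligo with NAC than in those given it alone. RNA of Npc1 oligo livers mixed into these samples would need a share of 58.5% and is argued against, since the 68 genes raised 2-fold by the oligo moved by 0.11 (0.01 to 0.17) where 0.85 was needed. Time of day cannot be told apart from an effect of NAC: with the clock components as covariates the change was -0.49 (-0.85 to -0.14, adjusted p = 0.195), and the clock genes themselves moved with NAC, which keeps it open. An effect of NAC on Npc1 or on the uptake of oligos could equally be at work and was not tested.

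In Npc1-/- mouse 3 at 5 weeks the level of Gpnmb was 9.87, against 10.6 to 10.7 in the other mice of its group. Among mice given the Npc1 oligo and NAC, mouse 3 stood apart with a Gpnmb level of 6.32 (others 9.61 to 9.78), a lipid-laden macrophage mean of 7.42 (8.65 to 8.93) and a lysosome mean of 8.77 (9.17 to 9.32), while its Npc1 level, 7.26, lay within its group's range of 6.68 to 7.51. Its array had the lowest median (5.35) and upper quartile (7.12) of all 78 arrays, and whether array quality sets it apart was not tested. The level of Sqle was 9.08 in Npc1-/- mouse 1 at 11 weeks (others 8.11 to 8.23) and 8.67 in Npc1+/+ mouse 2 at 9 weeks (7.40 to 7.58). The level of Saa1 was 11.2 in mouse 1 given the control oligo and NAC (others 12.0 to 12.3) and 8.65 in mouse 4 given the Npc1 oligo and NAC (10.7 to 11.5). Control oligo mouse 2 had a lysosome mean of 8.65 (8.76 to 8.80).

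The pancreas mean was 6.27 in Npc1-/- mouse 2 at 1 week (others 4.93 to 5.07), 5.87 in Npc1-/- mouse 4 at 5 weeks (4.83 to 4.93), 6.04 in Npc1+/+ mouse 1 at 5 weeks (4.91 to 5.08) and 6.02 in Npc1+/+ mouse 4 at 11 weeks (4.89 to 4.97). The skeletal muscle mean was 8.82 in Npc1-/- mouse 3 at 1 week (5.25 to 5.44), 5.38 in Npc1-/- mouse 1 at 7 weeks (lowest 5.28), 6.46 in Npc1+/+ mouse 3 at 7 weeks (5.31 to 5.41) and 5.15 in Npc1+/+ mouse 2 at 11 weeks (5.31 to 5.32). The mean correlation with the other mice of the group was 0.984 in Npc1-/- mouse 3 at 1 week (others 0.988) and 0.985 in mouse 3 given the control oligo and NAC (0.990 to 0.991).

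Effects differed between groups, by tests of the difference itself, in 4 contrasts. The genotype effect varied between ages for 3501 genes (highest of 99 other splits 2173) and had a slope with age for 3647 (highest other 1601). These splits exchanged the genotypes within each age and so removed the whole genotype effect, not only its change with age. They cannot decide whether chance is excluded for the change with age. Median slopes per week were 0.16 for macrophage genes, 0.23 for lipid-laden macrophage genes and 0.092 for neutrophil genes. The oligo effect differed with NAC for 575 genes (highest other 553, in a split that kept or mirrored the division by NAC under the control oligo, and 151 next). Of 100 splits 1, the real one, was as large, but the count was 528 with the replicate number as a block and 346 to 1037 with 1 array left out, a range wider than its margin over 553, so that chance is left open here. The genotype effect at 11 weeks and the oligo effect differed for 3528 genes, with a median of 1.67 for lipid-laden macrophage genes. Here 5 of 100 splits gave as many genes, up to 4449. Each of the 4 others kept or mirrored the division by genotype and so held the whole genotype effect, which does not show what chance gives. The highest of the 95 splits that broke this division was 1770, and whether chance can be excluded for the difference is left open.

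Probe sets without exactly 1 gene symbol, which no comparison used, held signal as well: 2184 of 6550 (33.3%) passed in the contrast averaged over ages and 265 of 6020 (4.40%) in the oligo contrast.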

How the results depend on the processing

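The alternatives that leave out mice with muscle or pancreas signal, and list tests without those mice, were chosen only after the result was seen, all others before. Of 1103 pairs of a named gene and a contrast, 0 changed direction under any alternative run, 117 lost their call when 1 array was left out, and 130 under another alternative, the thresholds of 0.01 and 2-fold aside. Of the list tests in 16 contrasts, 575 stayed on their side of the threshold with quantile normalization and 33 lost their call, 604 stayed with centring and 7 lost it, and 395 stayed with an estimated correlation and 229 lost it. The test changed direction for hepatocyte secreted products under the oligo with NAC (adjusted p = 0.873, quantile normalization) and for the pancreas list on fasting (adjusted p = 0.999 without fasted mouse 3, in a range of 8.37e-05 to 0.999 with 1 array left out), and the cause was not tested. Counts moved by less than 1.5 times with no filter or a stricter one, either scaling, the mean of probe sets, the intensity trend, the unmoderated test and all arrays in the fit. Genes below the filter on low signal were not tested. Of 420 called genes with several probe sets, 358 had the same sign in all of them.

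With an adjusted p under 0.01 in place of 0.05, a stricter test by construction, the counts were 323 at 1 week, 1069 at 3 weeks, 964 at 5 weeks, 2178 for variation between ages, 1549 for the oligo, 1967 for the oligo with NAC, 351 and 355 for NAC with the control and Npc1 oligo, 156 for their interaction, 26 for fasting, 1726 for the control oligo and 2305 for the genotype minus oligo difference. With a 2-fold change required as well they were 54, 159, 186, 392, 480 and 779 from 1 to 11 weeks, 238 averaged, 773 for variation between ages, 636 for the slope, 1127 for age in Npc1+/+ mice, 113 for the oligo, 177 with NAC, 26 and 46 for NAC, 53 for the interaction, 7 for fasting, 75 for the control oligo and 505 for the difference.

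With only the compared groups in the fit, which leaves fewer samples, the counts were 2028 for the oligo with NAC, 552 and 393 for NAC with the control and Npc1 oligo, 226 for the interaction and 159 for fasting. With array weights fasting gave 357, and the cause was not tested. Without 1-week Npc1+/+ mice 3 and 4 the 1-week count was 223, and the cause was not tested. Without the muscle-positive mouse, Npc1-/- mouse 3, it was 442 with the same 12638 genes tested (439 with the filter applied anew, which left 12617), and 7 list calls of that age were lost, and without both pancreas-positive mice the 3-week count was 1015, with 3 list calls lost and 1 gained, while without all 3 the averaged count was 6201 and the slope count 3509. The correlation of genotype and oligo effects was 0.53 without the filter (0.588 with it), and that of the oligo effects without and with NAC 0.57 (0.640 with it), from more genes near background. With an estimated correlation, a stricter test, the lists past the threshold were 2, 5, 5, 8, 5 and 4 from 1 to 11 weeks, 6 averaged, 3 for the slope, 1 for fasting, 1 for the difference and 0 in the other 6 contrasts.

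With 1 array left out in turn, the counts ranged from 396 to 911 at 1 week, 1352 to 1919 at 3 weeks, 1136 to 1564 at 5 weeks, 2688 to 3246 at 7 weeks, 3533 to 4136 at 9 weeks and 4351 to 4749 at 11 weeks. They ranged from 6486 to 6656 averaged, 3216 to 3747 for variation between ages, 3317 to 3689 for the slope, 6043 to 7054 for age in Npc1+/+ mice, 2098 to 2769 for the oligo, 2624 to 3253 with NAC, 562 to 1250 and 545 to 984 for NAC, 346 to 1037 for the interaction, 25 to 69 for fasting, 2354 to 3163 for the control oligo and 3135 to 3593 for the difference. Counts moved by over 1.5 times without Npc1-/- mouse 3 (439), Npc1+/+ mouse 3 (396) or mouse 4 (430) at 1 week, control oligo mouse 2 (587) or control oligo and NAC mouse 2 (562) for NAC with the control oligo, and Npc1 oligo mouse 4 (545) for NAC with the Npc1 oligo. For the interaction they did so without control oligo mouse 2 (373), control oligo and NAC mouse 2 (346) or mouse 3 (979) or Npc1 oligo and NAC mouse 4 (1037), and for fasting without untreated mouse 4 (26), fasted mouse 4 (25) or fasted mouse 5 (33).

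Replicate numbers do not pair the samples: deviations of same-numbered mice correlated at a mean r of 0.00147 in the age series (56 of 264 pairs over 0.1) and -0.0152 in the 12-week set (14 of 75), and best with their own number correlated at most 2 of 4 mice in the age series and at most 1 of 5 in the 12-week set, except for 4 of 5 in the control oligo contrast. With the number as a block the counts were 709, 1975, 1568, 3174, 4184 and 4944 from 1 to 11 weeks, 6637 averaged, 3440 for variation between ages, 3651 for the slope, 6698 for age in Npc1+/+ mice, 2583 for the oligo, 2973 with NAC, 943 and 767 for NAC, 528 for the interaction, 51 for fasting, 3052 for the control oligo and 3530 for the difference. The lists past the threshold under this block were 19, 22, 24, 21, 18 and 21 from 1 to 11 weeks, 23 averaged, 17 for the slope, 13 for the oligo, 17 with NAC, 11, 11 and 11 for NAC and the interaction, 10 for fasting, 15 for the control oligo and 19 for the difference.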

Other observations

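All tests of other splits in this part were chosen only after the result was seen, while the gene lists were fixed before. Averaged over the ages, further lists of immune and stress genes differed between the genotypes. Genes of antigen presentation rose in 7 of 9 cases, 7 adjusted over the list alone, with the MHC class II genes H2-Aa (1.17 ± 0.07), Cd74 (0.89 ± 0.07) and H2-Ab1 (0.75 ± 0.06). The list median was 0.21 (adjusted p = 0.00117, and adjusted p = 0.188 with an estimated correlation). Chemokine and cytokine genes rose in 7 of 13 cases and fell in 2 (7 and 2 adjusted over the list alone), with Ccl3 (1.54 ± 0.06) and Ccl6 (1.07 ± 0.05). The median was 0.17 (adjusted p = 0.00347, and adjusted p = 0.121 with an estimated correlation). Antioxidant and glutathione genes rose in 14 of 27 cases and fell in 8 (15 and 8 adjusted over the list alone), with the peroxidase gene Gpx3 (1.21 ± 0.08), Srxn1 (0.95 ± 0.07) and the haem oxygenase gene Hmox1 (0.91 ± 0.05). Their median was 0.17 (adjusted p = 0.0176, and adjusted p = 0.372 with an estimated correlation). Cell cycle genes rose in 18 of 27 cases and fell in 1 (19 and 1 adjusted over the list alone), with Mcm6 (0.71 ± 0.12) and Ccnd1 (0.56 ± 0.11). The median was 0.22 (adjusted p = 0.0015, and adjusted p = 0.372 with an estimated correlation). At 11 weeks the cell cycle mean was lower in Npc1-/- mice (5.49 against 5.62). The antioxidant mean was not higher at 1 week (9.44 against 9.51) or 3 weeks (9.79 in both).

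Neutrophil genes were lower in Npc1-/- pups at 1 week, in 5 of 14 cases (8 adjusted over the list alone), with Mmp8 (-0.77 ± 0.14) and Retnlg (-0.63 ± 0.14). Across the neutrophil list the median was -0.37 (adjusted p = 2e-06, and adjusted p = 0.094 with an estimated correlation). At 11 weeks they were higher in 13 of 14 cases, 14 adjusted over the list alone, with Lcn2 (2.48 ± 0.31), Ngp (1.63 ± 0.20) and S100a8 (1.28 ± 0.23). The neutrophil list had a median change of 0.64 (adjusted p = 4.42e-05, and adjusted p = 0.106 with an estimated correlation). Of 14 genes known as female-biased 7 fell and 3 rose at 11 weeks, with the same numbers adjusted over the list alone, among them Sult3a1 (-5.98 ± 0.25) and Hao2 (-3.58 ± 0.17) falling and Sult1e1 (5.09 ± 0.56) rising. Across the female-biased list the median was -0.49 (adjusted p = 0.0335, and adjusted p = 0.194 with an estimated correlation). That call ended with quantile normalization (adjusted p = 0.0881) and with centring (0.109). The list mean was 8.23 to 8.42 in Npc1-/- and 8.79 to 9.12 in Npc1+/+ mice. Over the 16 contrasts the lowest adjusted p of limma's camera was 0.113 for autophagy, 0.111 for B and plasma cells and 0.0846 for the growth hormone and IGF axis, so that none of these lists passed.

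Other splits of the same mice gave fewer genes than the real groups in these contrasts. At a single age the lowest share that these splits can reach is 1 of 35. The 1-week count also depended on Npc1+/+ mice 3 and 4, as given above. These tests were not adjusted for their number. They make chance unlikely, without excluding it, for each contrast but NAC with the control oligo. There the count ran from 562 to 1250 with 1 array left out. That range is wider than its margin over the highest other split, so that chance is left open. The highest of the 34 other splits was 136 against 719 at 1 week, 234 against 1989 at 3 weeks, 258 against 1588 at 5 weeks, 902 against 3195 at 7 weeks, 731 against 4190 at 9 weeks and 1514 against 4973 at 11 weeks, each real division being 1 of 35. With 100 splits drawn it was 1742 against 6642 for the averaged genotype effect, 2410 against 6730 for age in Npc1+/+ mice, 346 against 2688 for the oligo, 1515 against 3058 for the oligo with NAC, 537 against 1012 for NAC with the control oligo, 202 against 851 for NAC with the Npc1 oligo, 4 against 63 for fasting and 562 against 3132 for the control oligo.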
